A study of Homo sapiens with 2 samples.

How the data were processed

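Gene expression was measured on 2 microarrays of PC3 cells, a human cell line established from a bone metastasis of a prostate adenocarcinoma. One array held RNA of cells given the solvent DMSO and the other RNA of cells given 10 µM fluphenazine, a phenothiazine antipsychotic that blocks dopamine receptors. Per the labels' protocols, total RNA was purified with a column kit and labelled with biotin using a whole-transcript labelling kit. The duration of treatment is not given in the sources used here. The probe sets carry the identifiers of an Affymetrix array whose probes lie towards the 3' ends of transcripts. The labelling kit named in the labels was made for another kind of array, and how kit and array were combined is not given in the sources used here.

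Per the submitters' processing notes, Affymetrix Expression Console 1.4, Transcriptome Analysis Console 3.1 and RMA were used, with no role or order stated. The deposited table holds 1 log2 signal per probe set and array, judged from the range of its values, 1.60 to 14.28. After sorting, the 2 columns differed by a median of 0.0067 and by at most 0.13, so the authors' deposited log2 values share nearly one distribution. Background correction could not be varied, since probe intensities were not used here. A normalization of this kind shows only how a gene moved relative to the others on the array, not a change in total RNA.

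The table used here held 47693 probe sets. The platform annotation, dated 2016, named exactly 1 gene for 37151 of them and several genes for 1668. A further 8821 were unnamed here, apart from 59 control probe sets, a few of which the annotation also names. Only probe sets with 1 gene were used, which gave 18393 genes. Symbols were updated through the gene identifier for 18354 genes, and 39 kept the symbol of the annotation. For the 9562 genes with several probe sets, the one with the highest mean of both arrays was taken. A gene was analysed when the higher of its 2 values reached the median of that quantity over all genes, 6.19. This floor left 9197 genes. It is a rank, not a detection call.

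With 1 array per treatment there is no spread between cultures, so no test, p-value or standard error across samples was computed. The number of arrays limits the precision. As a description of noise within the arrays, the log2 differences of probe sets of one gene had a pooled SD of 0.13 over the 3669 genes with at least 2 probe sets above the floor. All differences had a robust SD of 0.14. Neither contains the variation between separate cultures.

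The difference reported for each gene is its log2 value on the fluphenazine array minus that on the DMSO array. Counts of genes used a 2-fold threshold. Before the data were examined, 36 gene lists, the floor, the threshold, the alternatives and the rule for named genes were fixed. The rule took the 15 genes with the largest positive and the 15 with the largest negative difference above the floor. From each list it took up to 4 members, those with the largest differences in the direction of the list's median and the one with the largest difference the other way. The text names part of these. Genes outside the rule are said to be so.

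Each list's median difference over its members above the floor was placed among 10000 random lists of the same size, matched on mean expression in 20 bins. A list is described as standing apart when its percentile was above 97.5 or below 2.5. That limit, and the minimum of 5 members above the floor that it requires, were set after the data were seen. The percentile describes these 2 arrays. Genes of one pathway vary together between any 2 cultures, so it is no test of the drug. The list procedure was tested on simulated data with 9197 genes that varied independently, unlike genes of one pathway. The shares below therefore need not hold for the real lists. Lists of 20 genes with no shift stood apart in 3% of 100 runs, those shifted by -0.1 in 77% and those shifted by 0.3 in 100%. For lists of 7 genes shifted by -0.1 the share was 29%.

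Alternatives were 3 other scalings of the arrays, the mean of a gene's probe sets, 2 other floors, a 1.5-fold threshold, counting every probe set, the mean of a list, random lists without matching, and leaving out each list's most extreme member. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and statsmodels 0.14.6 was used, and limma 3.58.1 in R 4.3.3 for quantile normalization. The genome build is not given in the sources used here and no coordinates were used. Some members of the lists are not analysed here.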

Results

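The series asked how fluphenazine acts on castration-resistant prostate cancer cells. It compared PC3 cells given 10 µM fluphenazine with PC3 cells given DMSO, with 1 array for each. No value below has an error between replicates, and every difference is between these 2 arrays. The median log2 signal over 47693 probe sets was 4.74 on the DMSO array and 4.73 on the fluphenazine array. Values of the 2 arrays correlated with r = 0.994 across the 9197 genes above the expression floor, which are not independent replicates.

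Few genes differed strongly. The gene with the largest positive difference was MMP10, a secreted matrix metalloproteinase, whose log2 signal was 4.50 with DMSO and 6.49 with fluphenazine, a 3.97-fold difference. Its DMSO value lay under the floor of 6.19. GDF15, a stress-induced cytokine, was 2.46-fold higher (7.46 against 8.76), and the inflammatory cytokine IL6 was 2.05-fold higher (9.62 against 10.66). The largest negative differences were those of SLC1A7, a glutamate transporter (6.39 with DMSO against 5.12), MX2, an interferon-induced GTPase (7.37 against 6.24, or 2.19-fold lower), and APLP1, a relative of the amyloid precursor protein (6.26 against 5.20). The fluphenazine values of SLC1A7 and APLP1 lay under the floor. Among genes above the floor, these 3 higher and 3 lower genes were all that reached 2-fold. At 1.5-fold there were 26 higher and 27 lower genes, and 99.4% of genes lay between.

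Among the other genes with the largest positive differences were the stress-induced transcription factors DDIT3 (CHOP), at 0.96 on the log2 scale, and ATF3, at 0.79. Also among them were the collagenase MMP1 at 0.75, the metalloproteinase ADAMTS6 at 0.98, the serpin SERPINB7 at 0.94 and the peptide hormone gene SPX at 0.91. The rest were SNRNP200, a spliceosomal helicase gene read here by 1 dim probe set, at 0.90, MILR1 at 0.89, the co-stimulatory ligand ICOSLG at 0.84, the histone deacetylase HDAC9 at 0.82, the prostaglandin-degrading enzyme HPGD at 0.78 and the cysteine-synthesis enzyme CTH at 0.74. The 2 probe sets of CTH gave 0.63 and 0.74, whereas those of ICOSLG above the floor disagreed, at 0.84 and -0.36. For GDF15 the dimmer probe sets, under the floor, gave 0.38 each, and for HDAC9 the 3 dimmer ones ranged from -0.21 to 0.50. The other 2 probe sets of HPGD above the floor gave 0.29 and 0.34.

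The other large negative differences included 2 genes known to respond to interferon, TRIM22 at -0.84 and the death ligand TNFSF10 (TRAIL) at -0.79. They also included the calcium-binding inflammatory protein S100A8 at -0.88, the squamous-cell serpin SERPINB3 at -0.87 and the citrullinating enzyme PADI3 at -0.76. HAS3, which makes hyaluronan, was at -0.79, PLAAT4 at -0.76 and ACOX2, a peroxisomal oxidase, at -0.69. SNORC was at -0.91, SH3TC2 at -0.83, LDB3 at -0.82 and HOXB2 at -0.69. A second probe set, under the floor, gave -1.27 for S100A8 and -0.92 for SERPINB3. For SLC1A7 the other 2 probe sets gave only -0.19 and -0.09. Of the 15 largest positive differences 6 had a DMSO value under the floor, and of the 15 largest negative ones 6 had a fluphenazine value under it.

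**Figure D1:**
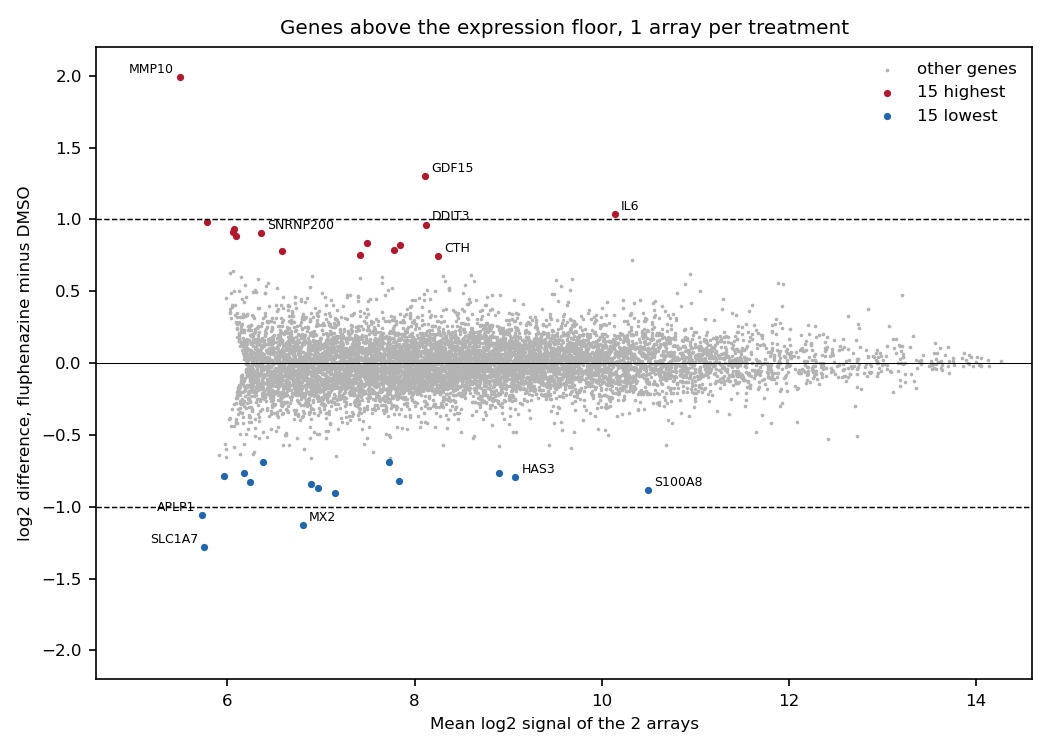
Each point is 1 of the 9197 genes above the floor, with the mean log2 signal of both arrays on the x axis and the log2 difference, fluphenazine minus DMSO, on the y axis; dashed lines mark 2-fold. MMP10, GDF15 and IL6 lie above the upper line, SLC1A7, MX2 and APLP1 below the lower one, and the 15 genes at each end are coloured.

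Genes of the integrated stress response, which the transcription factor ATF4 switches on when translation is restrained, were higher together. Of 28 members above the floor, 27 were higher with fluphenazine and 6 were at least 1.5-fold higher, led by GDF15 (1.30), DDIT3 (0.96) and ATF3 (0.79). ATF5 was the exception at -0.01. The list's median was 0.28, or 1.22-fold, with a 95% interval over members of 0.20 to 0.48, above all 10000 matched random lists (percentile 100). Endoplasmic reticulum chaperones and other XBP1 or ATF6 targets were higher by less, with a median of 0.08 over 19 members, 13 of them higher (interval -0.02 to 0.19, percentile 98.4). Their largest values were those of the co-chaperone DNAJB9 at 0.59, HERPUD1, of the degradation machinery, at 0.42, and the chaperone HSPA5 (BiP) at 0.26, while HSP90B1 was at -0.29. Averaging the probe sets put HERPUD1 at 0.19 and ATF3 at 0.42. That list did not stand apart without DNAJB9 (percentile 96.4) or when the probe sets of each gene were averaged (percentile 93.4).

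The list of p53 targets did not stand apart by its median of 0.02 (percentile 73.2), and did by its mean of 0.11 (percentile 99.8), to which GDF15 adds most. The members were split evenly, with 8 of 16 higher, among them GDF15, RRM2B (0.45) and the cell cycle inhibitor CDKN1A (0.30), and DDB2 at -0.19. Apoptosis regulators had a median of 0.06 (percentile 95.9). Of 2 inhibitors of apoptosis, BCL2A1 was at 0.52 and XIAP at 0.35 (0.12 with averaged probe sets). The pro-apoptotic genes CASP8 and BAX went opposite ways, at 0.20 (0.08 with averaged probe sets) and -0.15. The list of apoptosis regulators stood apart by its mean of 0.07 (percentile 98.3) and with averaged probe sets (0.08, percentile 99.5).

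Inflammatory genes and interferon-stimulated genes lay on opposite sides. Of 17 genes of the NF-kB and inflammatory list, 14 were higher with fluphenazine. The median was 0.28, or 1.21-fold (interval 0.12 to 0.34, percentile 100). IL6 was at 1.04, the neutrophil-attracting chemokines CXCL2 and CXCL8 were at 0.58 and 0.48, and the growth factor CSF1 was at -0.44. Averaging the probe sets put CXCL2 at 0.29 and CSF1 at -0.11. Immediate early genes had a median of 0.11 (interval 0.00 to 0.38, percentile 99.9), with 13 of 17 members higher, led by ATF3, CCN1 at 0.55 and the phosphatase DUSP1 at 0.54 (0.19 with averaged probe sets). DUSP4 was at -0.17. With the stricter floor, immediate early genes did not stand apart (percentile 91.3).

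Interferon-stimulated genes had the largest shift of any list. Of 24 members above the floor, 22 were lower with fluphenazine, 3 of them at least 1.5-fold: MX2 at -1.13 and the oligoadenylate synthetases OAS2 at -0.66 and OAS1 at -0.59. The median was -0.39, or 1.31-fold lower (interval -0.51 to -0.30), below all matched random lists (percentile 0). The transcription factor IRF1 was at 0.04. On the same array the bacterial poly-A spike-in controls were lower by a median of 0.22, as described with the controls at the end. All genes above the floor had a median of -0.01, so the spike-in drop is no measure of noise in the cells' genes.

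Mesenchymal and invasion genes went both ways. Their median was 0.06 over 17 members (percentile 94.9), with MMP1 at 0.75, the growth factor TGFB2 at 0.72 (0.30 with averaged probe sets), the collagenase MMP13 at 0.51 and the gelatinase MMP9 at -0.52. With the stricter floor the list stood apart, with a median of 0.12 over 10 members (percentile 99.1).

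**Figure D2:**
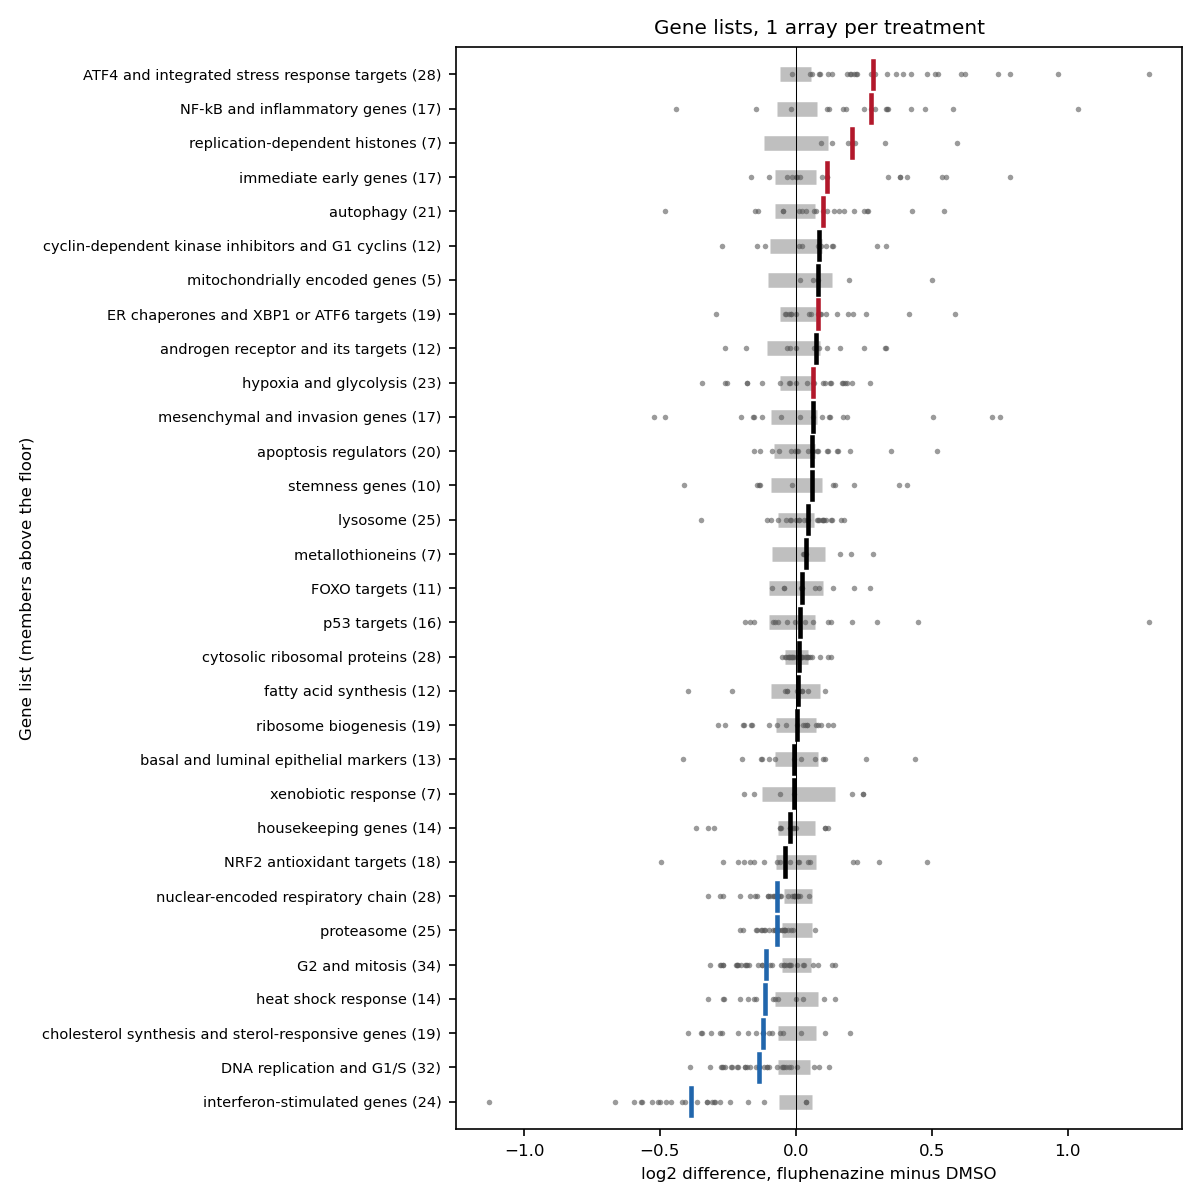
Each row is a gene list with at least 5 members above the floor (their number in brackets) and the x axis is the log2 difference, fluphenazine minus DMSO. Dots are members, grey bands hold 95% of the medians of matched random lists, and vertical lines are the list medians, red above and blue below their band: ATF4 targets (0.28) and inflammatory genes (0.28) lie highest and interferon-stimulated genes (-0.39) lowest.

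Genes of DNA replication and of mitosis were slightly lower with fluphenazine. In the DNA replication and G1/S list, 28 of 32 members were lower, with a median of -0.14, or 1.10-fold lower (interval -0.21 to -0.05, percentile 0). The replicative helicase subunits MCM2, MCM5 and MCM7 were at -0.39, -0.32 and -0.28, and the licensing factor CDT1 was at 0.12, or at -0.18 with its probe sets averaged. In the G2 and mitosis list, 27 of 34 members were lower, with a median of -0.11 (interval -0.19 to -0.03, percentile 0), among them the phosphatase CDC25C at -0.32, the topoisomerase TOP2A at -0.28 and the spindle protein PRC1 at -0.28. KIF23 was at 0.14. No member of either list reached 1.5-fold. The medians were smaller than the drop of the poly-A spike-in controls on the same array, while all genes above the floor had a median of -0.01. The spike-in drop is therefore no measure of noise in the cells' genes.

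Cyclin-dependent kinase inhibitors and G1 cyclins did not stand apart, with a median of 0.09 (percentile 96.2). GADD45A was at 0.33, CDKN1A at 0.30, CDKN1B at 0.14 and cyclin CCND3 at -0.27. With the stricter floor it stood just apart (0.12, percentile 97.7). Replication-dependent histone genes were higher in all 7 members above the floor, with a median of 0.21 (interval 0.09 to 0.59, percentile 99.97), led by H4C8 at 0.59 and H2BC21 at 0.33. Histone genes are near-identical, so their probe sets are uncertain, and 13 other members were under the floor and went both ways. With them the median was 0.10 (percentile 98.0).

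Cholesterol synthesis and sterol-responsive genes were lower in 16 of 19 members. The median was -0.12, or 1.09-fold lower (interval -0.28 to -0.06, percentile 0.01). TMEM97, which regulates the cholesterol transporter NPC1, was at -0.40, the sterol dehydrogenase NSDHL at -0.35 and HMGCS1, an early enzyme of the pathway, at -0.34, while the sterol sensor partner INSIG1 was at 0.20. The 3 probe sets of INSIG1 disagreed, from -0.25 to 0.20. With averaged probe sets the list median was -0.23. The poly-A spike-in controls were lower by a median of 0.22 on the same array, while all genes above the floor had a median of -0.01. The spike-in drop is therefore no measure of noise in the cells' genes. Fatty acid synthesis genes did not stand apart, with a median of 0.01 (percentile 60.4) and a mean of -0.04 (percentile 18.4). The elongase ELOVL6 was at -0.40 and the desaturase SCD at 0.11, or at -0.04 with averaged probe sets. Only 4 sterol efflux genes were above the floor, among them the cholesterol exporter ABCA1 at 0.56 and NR1H3 at -0.24. Their median of 0.01 was not stable, at 0.10 over 7 members with averaged probe sets and -0.21 without ABCA1. The 3 probe sets of APOE, another member, ranged from -0.21 to 0.99.

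Autophagy genes were higher in 16 of 21 members, with a median of 0.10 (interval 0.01 to 0.22, percentile 99.5). The phosphoinositide-binding protein WIPI1 was at 0.54, the cargo receptor SQSTM1 (p62) at 0.43 and BECN1 at 0.27, with ATG16L1 at -0.48. The probe sets above the floor for SQSTM1 spanned 0.43 to 0.60 and those for WIPI1 0.47 to 0.54, while those for BECN1 spanned -0.05 to 0.27. Lysosomal genes, 17 of 25 higher, had a median of 0.04 and did not stand apart (percentile 90.5). The peptidase TPP1 was at 0.18, NPC1 at 0.17 and the proton pump subunit ATP6V0A1 at -0.35, or at -0.08 with averaged probe sets.

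3 lists of protein folding, protein turnover and respiration were lower by small amounts. The heat shock list had a median of -0.11 with 10 of 14 members lower (interval -0.26 to 0.03, percentile 0.25), among them HSPB1 at -0.32, STIP1 at -0.27 and FKBP4 at -0.26 (-0.07 with averaged probe sets). The proteasome list had a median of -0.07 with 24 of 25 members lower (interval -0.11 to -0.05, percentile 0.29), led by PSMB3 at -0.20. Nuclear-encoded respiratory chain genes had a median of -0.07 with 23 of 28 members lower (interval -0.10 to -0.01, percentile 0.32), among them SDHA at -0.32 and NDUFV1 at -0.28. All genes above the floor had a median difference of -0.01. All 3 list medians were smaller in size than the 0.22 by which the poly-A spike-ins were lower on the same array. That drop is no measure of noise in the cells' genes, so the comparison does not explain the lists. Against random lists not matched on expression the last 2 did not stand apart, at percentiles 4.15 and 3.68. With averaged probe sets the respiratory chain list did not stand apart either, at -0.04 and percentile 23.4. Mitochondrially encoded genes had a median of 0.08 over 5 members (percentile 88.9), with ATP6 at 0.50, and stood apart by their mean of 0.17 (percentile 99.3).

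Hypoxia and glycolysis genes stood just outside the random range, with a median of 0.06 (interval -0.06 to 0.13, percentile 98.0), VEGFA at 0.27 and PFKFB4 at -0.35. The list did not stand apart under 6 of 8 alternatives, among them quantile normalization (percentile 93.4) and the mean of its members (percentile 65.8), nor against unmatched random lists (percentile 97.1). With averaged probe sets its median was -0.02 (percentile 40.9). Medians inside the random range were found for NRF2 antioxidant targets (-0.04, percentile 14.2), metallothioneins (0.04, percentile 74.9), FOXO targets (0.02, percentile 70.9), stemness genes (0.06, percentile 89.5), basal and luminal epithelial markers (-0.01, percentile 46.0) and xenobiotic response genes (-0.01, percentile 42.2). The same held for androgen-responsive genes (0.08, percentile 96.1), cytosolic ribosomal proteins (0.01, percentile 74.2), ribosome biogenesis genes (median 0.00, percentile 56.7, and mean -0.04, percentile 10.6) and housekeeping genes (-0.02, percentile 25.3). For 2 of these lists an alternative ended this. With averaged probe sets the ribosome biogenesis genes stood below the range, with a median of -0.09 (percentile 1.80). Stemness genes stood above it without a floor (0.12, percentile 99.3), with the stricter floor (0.14, percentile 99.2) and without the most extreme member (0.14, percentile 99.3).

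Of 31 lists with at least 5 members above the floor, 7 stood above and 7 below the range of random lists, where 1.55 would fall outside if each list were a random draw. The remaining 5 lists had too few members above the floor for such a statement. The list of receptors and calmodulin genes that fluphenazine binds had 19 of 21 measured members under the floor. The exceptions were TMEM97 (-0.40) and the histamine receptor HRH1 (0.09). From the calmodulin family only the calmodulin-like gene CALML3 was measured, and it was under the floor. The calmodulin genes themselves were not among the measured members, so the list says nothing about their expression. Neuroendocrine markers had 8 of 9 members under it, all but ENO2 (0.03). Wnt targets had 11 of 14 under it, with DKK1 at 0.28. Blood, endothelial and fibroblast markers, of cells that a PC3 culture should lack, had 15 of 17 under it, all but PECAM1 (-0.27) and COL1A1 (0.00).

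The control probe sets differed between the arrays as well. Poly-A spike-ins are bacterial transcripts added to the RNA before labelling. All 24 of their probe sets were lower on the fluphenazine array, by a median of 0.22 on the log2 scale. The deposited values share nearly one distribution, and the 9197 genes above the floor had a median difference of -0.01. The drop is therefore not a measure of noise in the cells' genes. The spike-in probe sets cover 4 transcripts by 2 probe set designs each. At the 5' ends the median difference was -0.34 and at the 3' ends it was -0.12. In each spike-in design the 5' probe set was also dimmer than the 3' one. A dim 3' probe set of the lys transcript, at 6.53 with DMSO, differed by -0.37. Position and signal level therefore cannot be told apart in the spike-ins. Hybridization controls, which are added after labelling, were lower by a median of 0.07, at 14 of 18 probe sets. Their median difference was -0.10 at the 5' ends and -0.02 at the 3' ends, and 7 of 8 probe set designs were lower at the 5' end. The human ACTB control differed by -0.13 at its 5' end and by 0.00 at its 3' end, and the GAPDH control by 0.06 and 0.03.

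**Figure D3:**
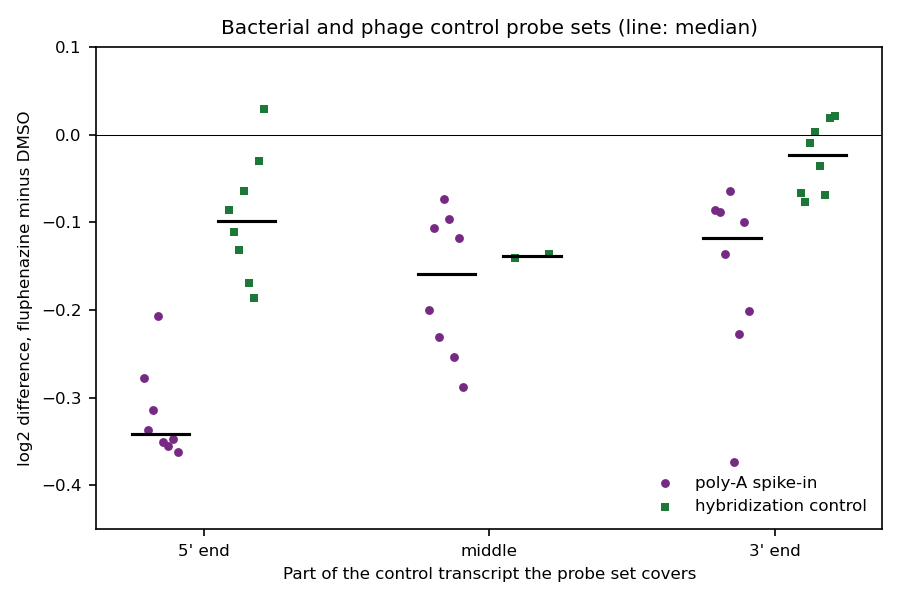
The x axis gives the part of the control transcript that a probe set covers and the y axis its log2 difference, fluphenazine minus DMSO; circles are poly-A spike-ins, squares hybridization controls and lines medians. The poly-A spike-ins lie lowest at the 5' end, with a median of -0.34 against -0.12 at the 3' end.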

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

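The tests below were written before their results were seen, except that the test for a culture difference was added afterwards for the interferon and the replication genes. The patterns themselves were picked after the list medians were known.

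The poly-A spike-in controls, outside the gene comparison, are bacterial transcripts added to the RNA, and they differed between the arrays. Their values are relative to the cells' own genes, so where their overall drop arose cannot be told from these arrays. The log2 difference between arrays at their 5' ends minus that at their 3' ends had a median of -0.17 over 8 probe set designs, 7 of 8 below 0. In the hybridization controls, which are added after labelling, it was -0.058, also with 7 of 8 below 0. In the cells' own genes the same comparison can be made only roughly, since probe positions were not used here and the dimmest probe set of a gene stands in for the one farthest from the 3' end. Over 3669 genes, the dimmest differed from the brightest by a median of -0.03 (95% interval -0.04 to -0.02). In each spike-in design the 5' probe set was also dimmer than the 3' one, so position and signal level cannot be told apart there either.

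The ATF4 targets were higher, against the direction of the spike-ins. Noise of single probe sets is argued against by the probe sets of the same genes that the list had not used: 17 probe sets of 13 genes had a median of 0.15 (interval 0.10 to 0.30), smaller than the 0.28 of the brightest probe sets but on the same side. A difference between the 2 cultures other than the drug, such as density or age of the medium, cannot be told apart from fluphenazine, because there is 1 array per treatment and more than 1 is needed. The treatment itself stays among the open explanations, as untested.

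The interferon-stimulated genes were lower. Their unused probe sets, 10 of 9 genes, had a median of -0.36 (interval -0.50 to -0.27), which argues against noise of single probe sets. Weaker signal towards the 5' end, as in the spike-ins, stays open as part of the shift. The size argues against it as the whole cause, if the cells' genes weaken no more steeply than the spike-ins. The list's brightest probe sets had a median of -0.39 (interval -0.51 to -0.30). The 5' minus 3' difference of the spike-ins was -0.25 at its lowest, and the dimmest minus the brightest probe set over 3669 genes was -0.03. Within genes the dimmest minus the brightest probe set was 0.013, but the interval of -0.22 to 0.21 over 9 genes is too wide to decide. A culture difference also stays open, with 1 array per treatment.

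All genes above the floor had a median difference of -0.01, and the replication and mitosis genes were lower by less than the spike-ins. The spike-in drop is no measure of noise in the cells' genes, so this comparison decides nothing. Unused probe sets of these genes had a median of -0.16 (31 probe sets of 27 genes, interval -0.21 to -0.12), so noise of single probe sets does not account for it. The dimmest minus the brightest probe set was -0.048 (interval -0.14 to 0.02, 27 genes), which neither shows nor excludes weaker signal towards the 5' end as a cause. Growth state of the 2 cultures and an effect of the drug cannot be told apart with 1 array per treatment.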

How the results depend on the processing

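No alternative here was added after the data were seen. The counts depended most on the floor and the threshold. The 3 genes at least 2-fold higher became 9 with no expression floor, 26 at 1.5-fold and 5 with every probe set counted, and the 3 lower genes became 14, 27 and 4. With the 75th percentile floor 2 higher and 0 lower genes were left. The mean of the gene's probe sets gave 3 higher and 5 lower genes, of which 2 and 2 were among the main ones. The 3 other scalings kept all 6 genes, and quantile normalization and loess each added ADAMTS6 to the higher ones, which made 4. These scalings are weak checks of the lists. Median centring moves all genes alike, so a list's place among random lists could hardly change under it. The arrays already shared nearly one distribution, which left little for quantile normalization and loess to change. Of 14 lists that stood apart, 9 did so under all 8 alternatives to the value of a list: ATF4 targets (0.22 to 0.37), inflammatory genes (0.23 to 0.29), autophagy, interferon-stimulated genes (-0.40 to -0.37), cholesterol synthesis (-0.23 to -0.11), DNA replication, mitosis, heat shock and proteasome. Of these 9, all but the proteasome, that is 8, also stood apart against unmatched random lists, where the respiratory chain and hypoxia lists did not. Averaging probe sets ended this for the endoplasmic reticulum and respiratory chain lists, and the stricter floor for immediate early genes. With the stricter floor the histones kept 4 members, under the minimum of 5, with a median of 0.16 (percentile 98.4). The hypoxia list reversed to -0.021 with averaged probe sets and kept its place under 2 of 8 alternatives; the cause was not tested. Some lists inside the random range in the main setting stood apart under an alternative: p53 targets, apoptosis regulators, cyclin-dependent kinase inhibitors, mesenchymal, stemness and mitochondrially encoded genes above it, and ribosome biogenesis below it. Of the other lists, the mean of the fatty acid list was -0.042, the Wnt median was -0.037 with averaged probe sets and -0.066 without a floor, and the 1 neuroendocrine gene was at 0.045, 0.052 and 0.05 under median centring, quantile normalization and loess. Averaging the probe sets moved 41 of 154 named genes by more than the robust SD of all differences. The other 575 of 616 values under 4 alternatives moved by less. Most of them say little about stability, since the 3 scalings had little to change and averaging cannot change a gene with 1 probe set. None of the genes at least 1.5-fold different reversed. With averaged probe sets GDF15 was at 0.69, HPGD at 0.41, HDAC9 at 0.31, ADAMTS6 at 0.62, SPX at 0.52, ABCA1 at 0.36, VEGFA at 0.14, BECN1 at 0.11, NPC1 at 0.26, PFKFB4 at -0.17, ATG16L1 at -0.32, STIP1 and CCND3 at -0.16, TOP2A at -0.15, TNFSF10 and LDB3 at -0.51 and -0.50, HAS3 at -0.49, SNORC at -0.56, SH3TC2 at -0.55, SLC1A7 at -0.52 and ICOSLG at 0.10, while 9 of the 41, all under 1.5-fold, took the other sign, among them CDT1 (-0.18) and INSIG1 (-0.044). No paired analysis was possible because each treatment has 1 array; for the same reason no array could be left out.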

Other observations

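The lists and genes in this part were chosen after the largest differences had been seen. The tests of the added lists were written before their values were looked at.

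Genes under the expression floor held further large differences, 6 higher and 11 lower by at least 2-fold among 9196 genes. Their signals were dim and no detection call was made, so these differences are uncertain. INHBE, an inhibin subunit gene, was at 1.27 and the cholesterol exporter ABCG1 at 1.15. TNFRSF11B (osteoprotegerin), a decoy receptor of the TNF family, was at -1.51, just under the floor with DMSO (6.17 against 4.66). The inflammasome sensor AIM2 was at -1.20. SERPINB4 was at -1.12, and it is a close copy of SERPINB3, so the probe sets of the pair are uncertain.

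Genes of antigen presentation were lower with fluphenazine in 11 of 14 members above the floor. The median was -0.19 (95% interval -0.25 to 0.00), with the immunoproteasome subunits PSMB9 at -0.33, PSMB10 at -0.26 and PSMB8 at -0.25 and the peptide transporter TAP1 at -0.19. TAP2 was at 0.00 and ERAP1 at 0.19. The hypothesis that they moved with the interferon-stimulated genes predicted a percentile of at most 2.5 among matched random lists, and it was 0 after rounding. These genes are themselves known to respond to interferon, and the interval reaches 0. Among the lower members were the related genes HLA-B, HLA-C, HLA-E, HLA-F and HLA-G, from -0.10 to -0.22. Whether their probe sets read one another's transcripts was not tested. The poly-A spike-in controls were lower by a median of 0.22 on the same array, more than this list, while all genes above the floor had a median of -0.01. The spike-in drop is therefore no measure of noise in the cells' genes.

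The hypothesis that aminoacyl-tRNA synthetase genes outside the ATF4 list were higher with it predicted a place above the range of random lists, and the percentile was 89.0, within it. Their median was 0.05 over 14 members, 9 of them higher (95% interval -0.05 to 0.15), so a shift as large as the 0.28 of the ATF4 targets lies outside the interval and a smaller one stays open. GARS1 was at 0.22 and SARS1 at 0.18, and VARS1 was at -0.23. Squamous differentiation genes were tried because S100A8, SERPINB3 and PADI3 were lower. Only 4 of 15 measured members were above the floor, with a median of -0.09 (percentile 5.72), which is under the minimum of 5 members and leaves the question open.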
